A study of Mus musculus with 8 samples.

How the data were processed

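The samples were myeloid cells sorted by FACS on the integrin subunit Cd11b from mouse bone marrow, 4 from control animals and 4 from experimental animals, each hybridised as biotin-labelled cRNA to an Affymetrix mouse array. The deposited table gives log2 values per probe set, and the submitters' processing notes name RMA (background correction, quantile normalization between arrays and summary of the probes of a probe set), without a version. The median of the tested values lay between 5.01 and 5.04 in all 8 arrays. Quantile normalization makes medians alike, so this does not tell whether an array stood apart in scale before it. Whether all 8 arrays were normalized together is not given in the sources used here.

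The table held 45101 probe sets. After 64 Affymetrix control probe sets were left out, 45037 were tested, of which 34945 carried 1 gene symbol, 932 several and 9160 none in the platform annotation used. Of the probe sets with 1 symbol, 34741 matched a gene of the RefSeq annotation of GRCm38.p6 by gene identifier, and no symbol changed through that match. Probe sets with several symbols or none are given by their identifier, and no coordinates are reported because that assembly is not the build of the array. For analyses of genes, each of 18193 genes was represented by its probe set with the highest mean over all 8 arrays.

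Differences are experimental minus control on the log2 scale, fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of adjusted p 0.05. Errors of differences of genes and probe sets are the moderated standard errors of that fit, and errors of group levels are SDs over 4 arrays. For single values of 4 against 4 arrays, a two-sided exact permutation test was run, whose smallest p is 0.0286. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 24 lists, with camera at an estimated correlation and fry beside it. The lists, written before the data were examined, held 548 genes, of which 504 were measured: DNA replication and nucleotide synthesis, G1/S regulators, E2F and pocket proteins, mitosis, DNA repair, p53 targets, apoptosis, 7 lists of myeloid granules, receptors, stages and regulators, interferon response, inflammatory cytokines, ribosome biogenesis, markers of erythroid, B, T and NK, megakaryocytic, eosinophil or mast, and dendritic cells, and immediate early genes as a sign of handling. Each list's members were also adjusted over the list alone.

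Genes named in the text follow a rule fixed before the data were examined. It takes every probe set of E2f1, E2f2 and E2f3, and the 10 largest rises and 10 largest falls among genes past the threshold whose arrays do not overlap between groups, without Riken, Gm-number or predicted loci. From each list it takes up to 4 members with the smallest p past the threshold (the 2 brightest where none passed), and members past the threshold against the direction of their list. Members of a list named beyond this rule were chosen after their values were seen.

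In 8 simulated arrays of 45037 probe sets with the means and spreads of these data and 200 changed probe sets above the median level, the fit of experimental against control recovered 23.9% of changes of 1.5-fold, 62.7% of 2-fold and 89.4% of 4-fold, with 2.5% false calls. The simulated probe sets varied independently, without a batch, and fewer were changed than were called in the data. These rates may therefore not carry over to the real fit. The number of arrays limits the precision.

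Same-numbered control and experimental arrays deviated together from their group means, with correlations across probe sets of 0.20 to 0.26 in all 4 pairs, so the numbers were treated as pairing the samples, and blocked values are given where they change a call or move a count by over 1.5 times. The pairing followed the style of the sample codes in the labels. Arrays of another number in the same code style (digit then letter for replicates 1 and 2, letter then digit for 3 and 4) correlated at 0.14 to 0.26, and arrays of the other style at -0.27 to -0.13. Code style was therefore handled as a batch that holds both groups. Principal component 1 held 33.0% of the variance and component 2 held 26.8%. Sex was read from Xist and Eif2s3y, which named the same sex in each array: 2 male and 2 female controls, 1 male and 3 female experimental samples. The arrays that share a code numeral, replicates 1 and 2 of each group, were 1 male and 1 female, so by inferred sex they are not the same animal, which the alternative that averages them does not take into account.

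Alternatives planned before the data were examined were median centring, quantile normalization, filters on dim probe sets, trended and robust variance, array weights, other ways of taking a gene's probe sets, replicate number or code style as a block, averaging arrays that share a code numeral, leaving out each array, other thresholds, an ordinary variance and other list tests. Fits within each code style and fits with inferred sex, alone or with code style, as a block were added after seeing the data.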

Results

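Expression was profiled in bone marrow cells positive for Cd11b, an integrin subunit carried by granulocytes and monocytes, from mice aged 8 weeks on a mixed FVB and C57BL6 background. All mice were labelled E2f1 null with floxed E2f3. The 4 control samples had intact E2f2 and no Cre in their genotype, and the 4 experimental samples were E2f2 null and carried the Mx-Cre transgene, whose promoter responds to interferon. Every mouse had received 5 injections of 250 µg of pIpC, a double-stranded RNA that induces interferon, and was killed 24 h after the last. From each sample, 2.5 µg of total RNA was labelled for the array. The comparison asks how expression in sorted myeloid cells differs when E2f2 and E2f3 are targeted beside E2f1, which encode the activating E2F transcription factors of the cell cycle. Every experimental sample and no control carried the Cre transgene, so effects of Cre itself cannot be told apart from those of the E2f genotype. The labels do not say that every sample came from a separate animal. By the sex read from Xist and Eif2s3y, control replicates 1 and 3 were male and 2 and 4 female, and experimental replicate 2 was male and the others female, so samples of different sex came from different animals. For samples of the same group and sex this stays open, and p-values measure the spread between these samples, which may be technical in part.

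E2f2 was lower in the experimental samples by 1 of its 2 probe sets. Probe set 1455790_at read 7.92 ± 0.19 in controls and 7.26 ± 0.21 in experimental samples (SD, n = 4 each), a difference of -0.66 ± 0.13 (SE, adjusted p = 0.0351), or 63.4% of the control level. The brighter probe set 1436434_at read 9.85 ± 0.28 and 9.31 ± 0.21, a difference of -0.55 ± 0.16 (SE) that did not pass (adjusted p = 0.107). In both probe sets all 4 experimental arrays lay below all 4 controls (two-sided exact permutation p = 0.0286, adjusted p = 0.0667 over the 7 probe sets of the 3 targeted genes). E2f3 read 7.60 ± 0.11 in controls and 7.88 ± 0.15 in experimental samples at 1434564_at (difference 0.29 ± 0.11, adjusted p = 0.201), with no overlap between the groups, and 5.57 ± 0.15 and 5.68 ± 0.14 at 1427462_at (difference 0.11 ± 0.11, adjusted p = 0.657). E2f1, labelled null in both groups, read 6.86 ± 0.16 and 7.44 ± 0.54 at 1417878_at (difference 0.58 ± 0.23, adjusted p = 0.236), 6.57 ± 0.33 and 7.05 ± 0.46 at 1431875_a_at (difference 0.48 ± 0.24, adjusted p = 0.345) and 3.83 ± 0.06 and 4.07 ± 0.21 at 1447840_x_at (difference 0.24 ± 0.11, adjusted p = 0.318). Where these probe sets lie relative to the deleted or floxed exons was not analysed here, and a probe set outside the deleted part checks nothing. At 1431875_a_at E2f1 passed with code style as a block (adjusted p = 0.0256; 0.0256 to 0.603 over the alternatives), and at 1417878_at it passed without experimental replicate 2 (0.0499; 0.0499 to 0.444 over the alternatives). The call of E2f2 at 1455790_at depended on the arrays used: without 1 array its adjusted p lay between 0.0343 and 0.0951, and it passed only without experimental replicate 2 or 4.

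**Figure D1:**
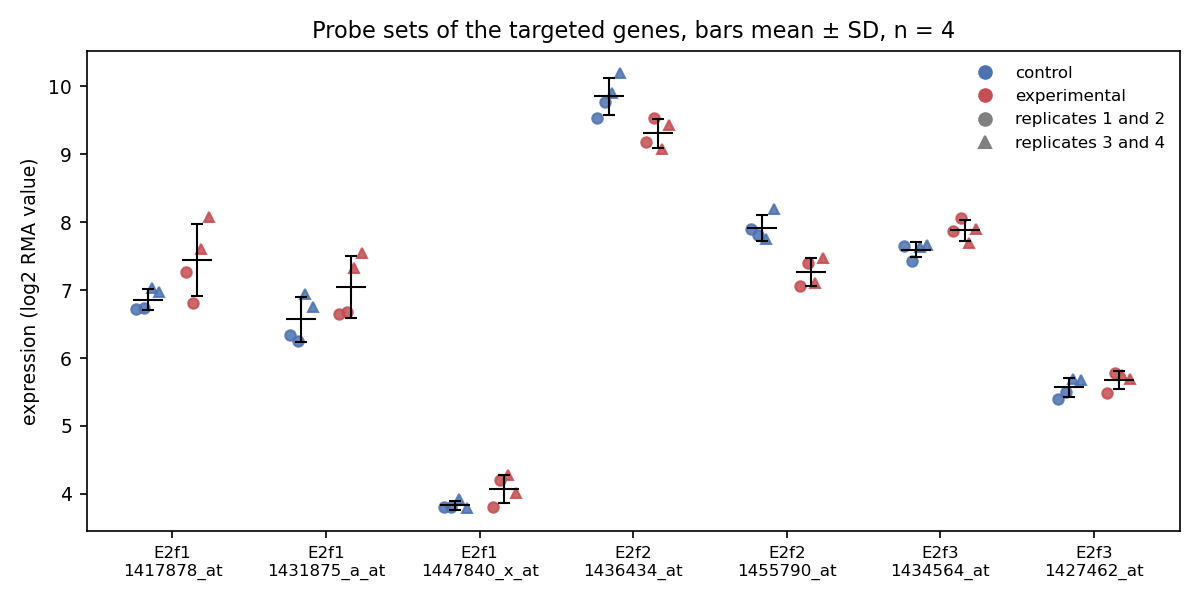
Log2 RMA value of each probe set of E2f1, E2f2 and E2f3 in the 4 control and 4 experimental arrays, with circles for replicates 1 and 2, triangles for replicates 3 and 4, and bars for mean ± SD. All experimental arrays lie below all controls at both E2f2 probe sets (means 7.26 against 7.92 and 9.31 against 9.85).

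Of 45037 probe sets, 466 rose and 696 fell in the experimental samples, together 1162, with the limma fit at adjusted p 0.05. Among genes with 1 representative probe set, 278 rose and 354 fell, and 75 of the rises and 106 of the falls were at least 2-fold. The largest rises were Stfa3, a cysteine protease inhibitor of the stefin family (9.36-fold, log2 difference 3.23 ± 0.25 SE, n = 4 per group), Ncmap (7.12-fold, 2.83 ± 0.16), which lies among the 40 measured genes on either side of E2f2, and Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (4.76-fold, 2.25 ± 0.18). Ecm1 (2.21), Perp (2.19), Ptpn3 (2.10), the apelin receptor gene Aplnr (2.06), Cd200r4 (1.84), Npl (1.83) and Cap1 (1.79) followed on the log2 scale. The largest falls were Ms4a1, which encodes the B cell antigen CD20 (7.04-fold, log2 difference -2.82 ± 0.42), Hpgd, an enzyme of prostaglandin breakdown (6.05-fold, -2.60 ± 0.47), and Fcmr, the Fc receptor for IgM (5.65-fold, -2.50 ± 0.42). Spib (-2.48), Cd209a (-2.37), Ighv14-2 (-2.35), Ly6d (-2.25), E2f7 (-2.24), Ppbp (-2.24) and Trib2 (-2.20, with 1 of its 3 probe sets of the opposite sign) completed them. Of probe sets without a gene name here, 39 rose and 57 fell, led by 1452426_x_at (-3.90) and 1433741_at (3.48).

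The count was 2277 with replicate number as a block (1000 higher, 1277 lower) and 2582 with code style as a block (1136 higher, 1446 lower). It was 466 without control replicate 1, 395 without control replicate 2, 738 without control replicate 3, 421 without control replicate 4, 629 without experimental replicate 1, 1744 without experimental replicate 2 and 586 without experimental replicate 4. Of 69 named genes past the threshold, 38 passed in all 8 fits that leave out 1 array, among them Stfa3, Ncmap, Cdkn1a, Ecm1, Ms4a1, Spib, E2f7 and Ppbp, while 18 passed in fewer than 4: Atf3, Birc2, Cdk6, Chek1, Csf1, Fas, Id1, Ifit2, Ighv14-2, Igsf6, Il7r, Ms4a3, Nr4a1, Rad54l, Siglecf, Topbp1, Tubb1 and Perp, the last (adjusted p = 0.0528 to 0.110) in none.

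Genes of DNA replication and nucleotide synthesis, a list of classical E2F targets, rose as a group. Of 44 measured, 26 rose and 1 fell (34 and 2 adjusted over the list alone), with a median log2 difference of 0.57. They included the licensing genes Cdt1 (1.23 ± 0.10 SE, 2.35-fold, n = 4 per group, with 1 of its 3 probe sets of the opposite sign), Orc1 (1.31 ± 0.11, 2.47-fold) and Cdc6 (1.05 ± 0.09, 2.07-fold) and the histone chaperone gene Chaf1b (1.10 ± 0.10, 2.15-fold). Each of Mcm2 to Mcm7, which encode the replicative helicase, rose as well, by 0.76 for Mcm7 to 1.09 for Mcm3. Tyms, which encodes thymidylate synthase, fell against its list (-0.59 ± 0.09), but not past the threshold without control replicate 4. Its level was low, at 5.63 in controls and 5.03 in experimental samples, near the array medians of 5.01 to 5.04. Pcna (0.03), Rrm2 (-0.10) and Tk1 (0.13) did not pass. For the list as a whole camera gave adjusted p = 2.4e-24, and adjusted p = 0.0928 with an estimated correlation. The mean difference was 0.60 within replicates 1 and 2 and 0.55 within replicates 3 and 4. The ratio of 3' to 5' signal of beta-actin, a sign of RNA integrity, was also higher in every experimental array than in every control (mean log2 ratio 0.44 against 0.30). The same ratio of Gapdh overlapped between the groups (mean log2 ratio -0.09 against -0.12).

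Mitosis and G2/M genes moved the other way: of 34 measured, 10 fell and none rose (20 adjusted over the list alone), with a median of -0.34. The spindle and kinetochore genes Nusap1 (-0.91 ± 0.11 SE, n = 4 per group), Nuf2 (-0.80 ± 0.11), Ndc80 (-0.88 ± 0.12) and Cenpf (-0.98 ± 0.14) fell, as did the proliferation marker Mki67 (-0.80) and Top2a (-0.71). The list test gave adjusted p = 1.0e-13, and adjusted p = 0.151 with an estimated correlation. The mean difference was -0.44 within replicates 1 and 2 and -0.34 within replicates 3 and 4. The actin ratio (0.44 against 0.30) separated the groups as the mean of this list did. The number that fell was 5 without control replicate 1, 3 or 4 or experimental replicate 4, and 6 without control replicate 2 or experimental replicate 1. Mki67 passed in all 8 fits that leave out 1 array and Top2a in 2 of them, without control replicate 2 or experimental replicate 3 (adjusted p = 0.0260 to 0.100).

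Regulators of the G1/S transition went both ways. Of 20, 2 rose (Cdkn1a and the kinase gene Cdk6, 0.81 ± 0.17 SE) and 3 fell: Cdkn2c, which encodes the inhibitor p18 (-1.81 ± 0.09, 3.51-fold, n = 4 per group), the cyclin E2 gene Ccne2 (-1.10 ± 0.17) and Ccna2 (-0.53 ± 0.11). Among the fits that leave out 1 array, Cdk6 passed only without control replicate 3 or experimental replicate 2, and Ccna2 only without experimental replicate 3 (adjusted p = 0.0316 to 0.118). Adjusted over the list alone, 3 rose and 5 fell, and camera gave adjusted p = 0.629, with a median of 0.02 but a test and a mean below 0 (means of -0.03 and 0.03 within the code styles). Of 13 genes of the E2F, DP and pocket protein families, each by its brightest probe set, E2f7, an atypical E2F that represses transcription, passed alone (-2.24 ± 0.24 SE, 4.74-fold lower). E2f2 passed at its dimmer probe set only, and 2 genes were lower with the mean of a gene's probe sets or its most variable one. E2f8 (-0.13), E2f4 (0.22), Rb1 (-0.16) and Rbl1 (0.27) did not. Adjusted over the list alone, E2f7 and E2f2 passed, both lower. Camera gave adjusted p = 0.810, with a median of 0.18, a mean of -0.09 (-0.05 and -0.13 within the code styles) and an upward test.

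Target genes of p53 were higher as a list: of 23, 6 rose and 1 fell (12 and 3 adjusted over the list alone), with a median of 0.29. Beside Cdkn1a, the polymerase gene Polk (0.95 ± 0.09 SE, n = 4 per group), Phlda3 (1.16 ± 0.13), the proapoptotic gene Bbc3 (0.87 ± 0.11), Ccng1 (0.84) and Perp rose, while the death receptor gene Fas fell (-0.66 ± 0.14; past the threshold without experimental replicate 4 and in no other fit that leaves out 1 array). Mdm2 (0.11) did not pass. By camera the list had adjusted p = 9.0e-05, and adjusted p = 0.0904 with an estimated correlation, with means of 0.43 and 0.42 within the code styles; the actin ratio (0.44 against 0.30) separated the groups as this list's mean did. With the replicate block 8 rose and 2 fell. Ccng1 passed only without experimental replicate 2, 3 or 4 (adjusted p = 0.0308 to 0.0930 over the fits that leave out 1 array). DNA repair and checkpoint genes had 3 of 21 higher and none lower (10 higher adjusted over the list alone): Topbp1 (0.63 ± 0.12), Rad54l (0.64 ± 0.12) and the checkpoint kinase gene Chek1 (0.65 ± 0.12). The repair list had camera adjusted p = 1.0e-05, and adjusted p = 0.299 with an estimated correlation, with means of 0.26 and 0.35. The number was 5 with the replicate block, 0 without control replicate 2 or 4 or experimental replicate 1, and 1 without control replicate 3 or experimental replicate 3 or 4. In the apoptosis list, Birc2 alone of 22 genes passed (-0.46 ± 0.10), also when adjusted over the list alone (camera adjusted p = 0.701, means of -0.0003 and 0.10), and it passed only in the fit without experimental replicate 2 among those that leave out 1 array.

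**Figure D2:**
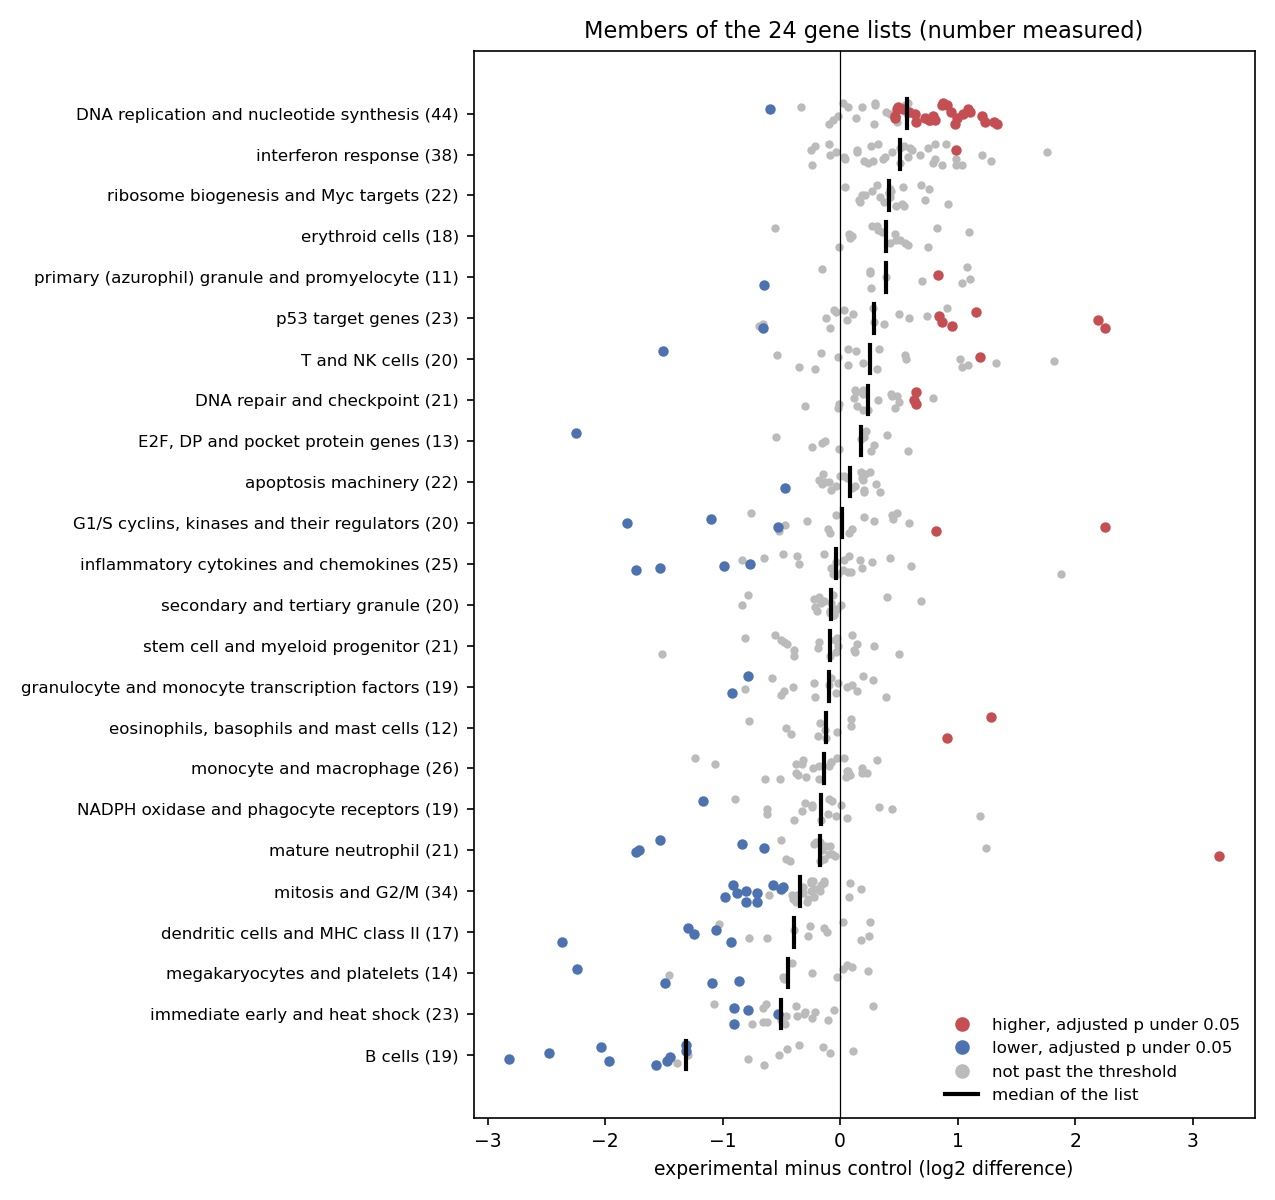
Log2 difference, experimental minus control, of each measured member of the 24 gene lists, with red and blue points for members past adjusted p 0.05, grey points for the others and a black bar at the list's median. Replication genes lie mostly to the right (median 0.57), and mitosis (-0.34) and B cell genes (-1.31) to the left.

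Among granulocyte lists, the mature neutrophil genes were lower: of 21, 5 fell and 1 rose (5 and 2 adjusted over the list alone), with a median of -0.17. The C-type lectin receptor gene Clec4d (-1.71 ± 0.15 SE, 3.28-fold, n = 4 per group), Csf3r, the receptor for G-CSF (-0.65 ± 0.09), and Il1b (-1.53 ± 0.24) fell with Ptgs2 and Ccl6, against the rise of Stfa3. The neutrophil list had camera adjusted p = 9.7e-05, and adjusted p = 0.0928 with an estimated correlation, with means of -0.20 and -0.26 within the code styles. In it 2 rose with the replicate block and without experimental replicate 2, and Ccl6 did not pass without control replicate 2 (adjusted p = 0.0534; 0.0214 to 0.0534 over the fits that leave out 1 array). Primary granule and promyelocyte genes had a median of 0.39, with Ms4a3 higher (0.83 ± 0.16) and Igsf6 lower (-0.65 ± 0.14) of 11 (4 and 1 adjusted over the list alone; 4 and 1 with the replicate block). Mpo (0.27) and Elane (0.26), which encode azurophil granule proteins, did not pass. This list had camera adjusted p = 0.0109, and adjusted p = 0.433 with an estimated correlation, means of 0.62 and 0.31, and no call without control replicate 1 (adjusted p = 0.0520). Without 1 array, 0 to 4 of its genes rose, with the highest number without experimental replicate 2, and Igsf6 passed only in that fit. Of 20 secondary and tertiary granule genes none passed (1 higher and 1 lower adjusted over the list alone and with the replicate block), with Camp at -0.13 and Lyz2 at -0.05. Both have mean levels (14.39 and 14.31) close to the highest value of each array (14.36 to 14.54), where a change may not be measurable, as do Ltf (14.29), Ngp (14.23) and Lcn2 (14.20). Its camera adjusted p was 0.0445 (adjusted p = 0.525 with an estimated correlation; means of -0.06 and -0.16), and 0.0520 to 0.235 in the 5 fits that lost the call, without control replicate 1, 2 or 4 or experimental replicate 3 or 4. The call was also lost with the mean of a gene's probe sets (adjusted p = 0.0709), with its most variable probe set (0.0864), among probe sets above the median level (0.129) and among those with a mean of at least 6 (0.165; 0.00366 to 0.525 over the alternatives).

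Monocyte and macrophage genes had no member of 26 past the threshold, nor adjusted over the list alone, with Lgals3 at -0.02 and Psap at 0.04 (camera adjusted p = 0.0678). Their mean difference was -0.64 within replicates 1 and 2 and 0.25 within replicates 3 and 4, opposite in sign. The camera test passed without control replicate 4 (adjusted p = 0.0131), experimental replicate 3 (0.00661) or experimental replicate 4 (0.0171). Within replicates 1 and 2 alone it passed at adjusted p = 3.0e-07 and within replicates 3 and 4, in the opposite direction, at adjusted p = 0.0113. It also passed with median centring (0.0452), with inferred sex as a block (0.0376) and with code style and sex as blocks (0.0326; adjusted p = 3.0e-07 to 0.575 over the alternatives). Stem cell and progenitor genes had none of 21 past it (1 higher and 7 lower adjusted over the list alone; 4 lower with the replicate block), with Spi1 at -0.03 and Myb at -0.01. For it camera gave adjusted p = 0.0370 (adjusted p = 0.151 with an estimated correlation; means of -0.23 and -0.19), lost without experimental replicate 2 (0.0856) or 3 (0.0976). Quantile normalization (0.0601) and tests of only probe sets above the median level (0.129) or of those with a mean of at least 6 (0.165) ended it too (adjusted p = 0.0156 to 0.165 over the alternatives). Of 19 myeloid transcription factors, Id3 (-0.92 ± 0.14 SE) and Id1 (-0.78 ± 0.16), inhibitors of basic helix-loop-helix factors, fell (5 lower adjusted over the list alone; 4 with the replicate block and without experimental replicate 2, and 1 in the other fits that leave out 1 array, except without control replicate 1), with camera adjusted p = 0.0103, and adjusted p = 0.0928 with an estimated correlation (means of -0.29 and -0.13). The call was lost when only probe sets above the median level (adjusted p = 0.0640) or only those with a mean of at least 6 (0.142; 0.00401 to 0.142 over the alternatives) were tested. Id3 also lies among the 40 measured genes on either side of E2f2. Of 19 NADPH oxidase and phagocyte receptor genes, Clec7a, the receptor Dectin-1, fell (-1.17 ± 0.21). In that list 1 rose and 3 fell adjusted over the list alone and with the replicate block (camera adjusted p = 0.00674, adjusted p = 0.40 with an estimated correlation, means of -0.22 and -0.12). Clec7a did not pass without control replicate 1, 2 or 4 or experimental replicate 1, and 3 fell without experimental replicate 2.

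Marker genes of B cells were the most strongly lower list by median (-1.31). Of 19, 9 fell and none rose (13 adjusted over the list alone): the kinase gene Blk (-1.32 ± 0.13 SE, n = 4 per group), the antigen receptor component gene Cd79a (-1.57 ± 0.16, 2.97-fold), Fcrla (-2.03 ± 0.21) and Spib (-2.48 ± 0.30, 5.57-fold) among them. The immunoglobulin genes Ighm (0.11 ± 0.34) and Jchain (-0.52 ± 0.73), the brightest of the list, and the pre-B cell genes Vpreb1 (-0.08) and Igll1 (-0.15) did not pass. The B cell list had camera adjusted p = 8.4e-13, and adjusted p = 0.0928 with an estimated correlation. It had means of -1.22 and -1.10 within the code styles. The means of the B cell, dendritic and megakaryocyte lists separated the groups, as did the actin ratio (0.44 against 0.30). The number of B cell genes that fell was 5 without control replicate 4. In the dendritic cell and MHC class II list, 5 of 17 fell (7 adjusted over the list alone): Cd209a (-2.37 ± 0.32), Siglech, a marker of plasmacytoid dendritic cells (-1.29 ± 0.20), Ccr7 (-0.93 ± 0.15), Ccr9 (-1.24 ± 0.23, with 2 of its 5 probe sets of the opposite sign) and the invariant chain gene Cd74, which passed only without control replicate 4 or experimental replicate 2 among the fits that leave out 1 array (adjusted p = 0.0156 to 0.112). This list had camera adjusted p = 7.0e-05, and adjusted p = 0.0928 with an estimated correlation (means of -0.56 and -0.59). The number was 2 without control replicate 2 and 3 without control replicate 4 or experimental replicate 1. Megakaryocyte and platelet genes had 4 of 14 lower (7 adjusted over the list alone), namely the platelet chemokine genes Pf4 (-1.49 ± 0.12) and Ppbp (-2.24 ± 0.34), Vwf (-0.86 ± 0.14) and Tubb1 (-1.09 ± 0.19), with camera adjusted p = 1.2e-05, and adjusted p = 0.0928 with an estimated correlation (means of -0.59 and -0.60). That list lost its call when only probe sets with a mean of at least 6 were tested (adjusted p = 0.0544; 4.1e-07 to 0.0928 over the alternatives). The number was 2 without control replicate 2.

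Lists of other cell types had medians above 0 or few genes past the threshold. Of 20 T and NK cell genes, Cd5 rose (1.19 ± 0.18 SE) and the interleukin 7 receptor gene Il7r, also expressed in B cell precursors, fell (-1.51 ± 0.30; 8 higher and 1 lower adjusted over the list alone, 4 and 1 with the replicate block). The T and NK list, with a median of 0.25, had camera adjusted p = 0.00674, and adjusted p = 0.433 with an estimated correlation, with means of 0.35 within either code style. It lost its call when only probe sets with a mean of at least 6 were tested (adjusted p = 0.108; 5.0e-05 to 0.433 over the alternatives). In this list 6 rose without experimental replicate 2 and 2 without control replicate 3, and Il7r passed only without control replicate 2. None of 18 erythroid genes passed, nor adjusted over the list alone (1 higher with the replicate block), with Car2 at 0.11 and Tfrc at 0.58. The erythroid list's camera adjusted p was 0.00761 (adjusted p = 0.540 with an estimated correlation; means of 0.66 and 0.08), and 0.443 without experimental replicate 1. Of 12 eosinophil, basophil and mast cell genes, the eosinophil genes Epx (0.91 ± 0.12) and Siglecf (1.28 ± 0.25) rose (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.629, with a median of -0.12, a mean of 0.01 and a downward test; means of 0.23 and -0.22 within the code styles). Siglecf passed only in the fits without experimental replicate 2, 3 or 4.

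**Figure D3:**
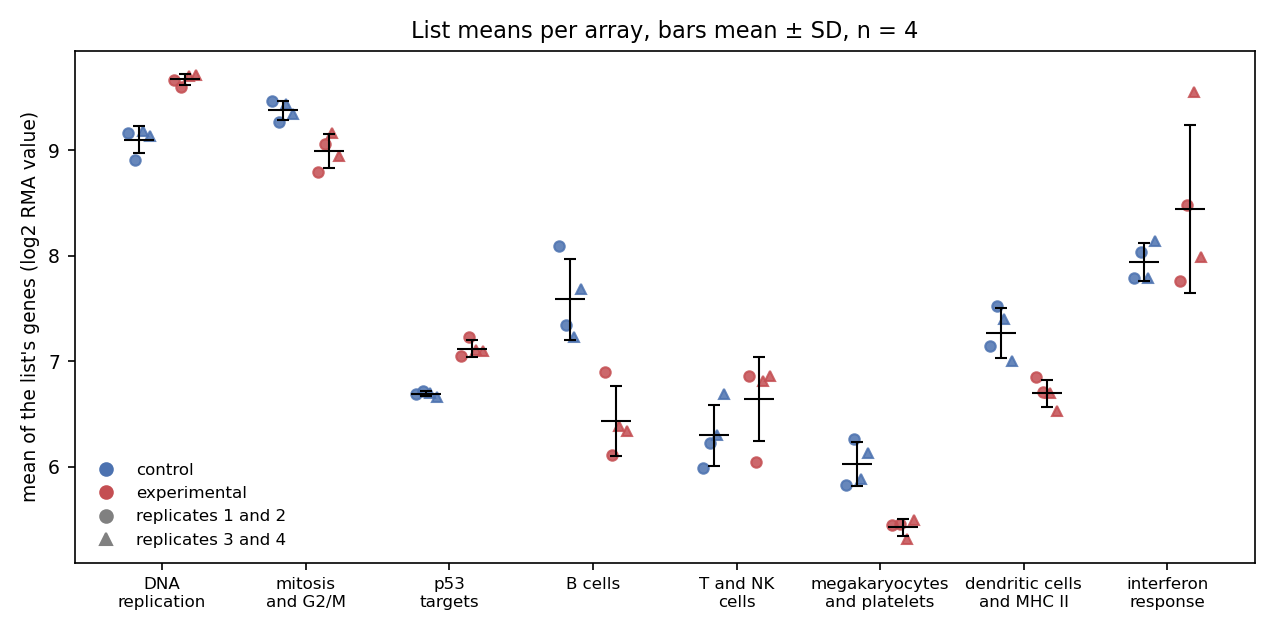
Mean log2 RMA value of the measured genes of 8 lists in each array, with circles for replicates 1 and 2, triangles for replicates 3 and 4, and bars for mean ± SD. The groups separate in the replication, mitosis, p53, B cell, megakaryocyte and dendritic lists, and the interferon mean of experimental replicate 3 (9.55) lies above the other 7 arrays.

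Interferon response genes had 1 of 38 higher, Ifit2 (0.99 ± 0.21 SE), and a median of 0.51 (7 higher adjusted over the list alone; 4 with the replicate block). The interferon list had camera adjusted p = 2.8e-05, and adjusted p = 0.512 with an estimated correlation, with means of 0.21 and 0.80 within the code styles. Of the fits that leave out 1 array, Ifit2 passed only in that without experimental replicate 4. The number of its genes that rose was 2 in that fit, 1 without control replicate 4 or experimental replicate 1, and 0 in the others. Without experimental replicate 3 the mean difference went from 0.50 to 0.14 and the adjusted p was 0.280. Ribosome biogenesis and Myc target genes had none of 22 past the threshold, nor adjusted over the list alone (2 higher with the replicate block), with Ldha at 0.27 and Npm1 at 0.43. Its camera test gave adjusted p = 0.000115, and adjusted p = 0.496 with an estimated correlation (means of 0.21 and 0.64; 2 higher without experimental replicate 2). Of 25 inflammatory cytokine genes 4 fell: the NF-kappaB inhibitor gene Tnfaip3 (-0.99 ± 0.15), Il1b, the prostaglandin synthase gene Ptgs2 (-1.74 ± 0.29) and Csf1 (-0.77 ± 0.15). Adjusted over the list alone 5 fell and 2 rose (2 rose with the replicate block; camera adjusted p = 0.115, means of -0.09 and -0.25), and 2 fell without control replicate 4. Immediate early and heat shock genes, which can follow handling of cells, had 4 of 23 lower (10 adjusted over the list alone; 8 with the replicate block): Ier2 (-0.53 ± 0.09), Zfp36 (-0.78 ± 0.14), Nr4a1 (-0.90 ± 0.19) and Atf3 (-0.90 ± 0.19). This list had camera adjusted p = 7.2e-08, and adjusted p = 0.0928 with an estimated correlation, with means of -0.58 and -0.38. The number was 0 without control replicate 4 or experimental replicate 4, 1 without control replicate 2 or experimental replicate 1, 2 without control replicate 1 or 3, and 7 without experimental replicate 2.

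Altogether camera placed 18 of the 24 lists past adjusted p 0.05, 8 higher and 10 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.0904, and 11 passed with fry, which asks whether a list's genes move on balance in 1 direction. Within replicates 1 and 2 alone, camera no longer placed the secondary granule (adjusted p = 0.505), stem cell (0.101), interferon (0.149) and ribosome (0.0761) lists past the threshold. Within replicates 3 and 4 alone this held for the primary granule (0.0743), myeloid transcription factor (0.109) and erythroid (0.443) lists, while the inflammatory list passed (0.0486). In 11 lists the mean of every experimental array lay on 1 side of every control array (two-sided exact permutation p = 0.0286, adjusted p = 0.0623 over 24 lists). The 3' to 5' ratio of beta-actin separated the groups as these 11 lists did, at 0.27 to 0.32 on the log2 scale in controls and 0.34 to 0.54 in experimental arrays (two-sided exact permutation p = 0.0286). That of Gapdh overlapped between the groups, at -0.14 to -0.09 in controls and -0.16 to 0.03 in experimental arrays (two-sided exact permutation p = 0.743).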

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

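The rule for single arrays far from the others of their group was set before the data were examined, and no test was added here after the results were seen. In 14 of 220 groups of 4 values (named genes, targeted probe sets and list means), 1 array lay far from the other 3 by Dixon's ratio, against 11 expected by chance; 7 of the 14 were in controls and 7 in experimental samples.

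Experimental replicate 2 stood apart in 4 of them. It read 12.7 for Cap1 (others 11.7 to 11.9), 4.66 for Spib (5.94 to 6.08), 4.39 for Ccr9 (5.21 to 5.31) and 6.05 for the mean of the T and NK cell list (6.81 to 6.86). Experimental replicate 1 read 5.24 for Tyms (4.95 to 4.98), and experimental replicate 4 read 10.32 for Topbp1 (10.50 to 10.54) and 6.20 for the mean of the inflammatory list (6.34 to 6.37).

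Control replicate 1 read 11.08 for Spi1 (others 11.46 to 11.49), 8.46 for Id1 (8.88 to 8.95) and 5.35 for Tubb1 (6.19 to 6.26). Control replicate 2 read 7.43 for E2f3 at 1434564_at (7.63 to 7.67) and 8.15 for the mean of the G1/S list (8.35 to 8.36). Control replicate 3 read 3.93 for E2f1 at 1447840_x_at (3.79 to 3.81), and control replicate 4 read 7.46 for Cd209a (8.82 to 8.94).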

How the results depend on the processing

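Fits within a code style, with inferred sex as a block, and with code style and sex together were chosen after seeing the data. Of 69 named genes past the threshold, none changed sign in an alternative that tested it (63 when only probe sets above the median level were used, and 53 with a mean of at least 6), and all 69 stayed past it with replicate number or code style as a block. In all 632 genes past the threshold the arrays of the groups did not overlap. Fits that leave out, split or average arrays could therefore not change a sign, nor could these blocks, which hold both groups equally. Replicate number as a block gave 2277 calls (1000 higher, 1277 lower; 1123 of the 1162 shared), code style 2582 (1136 and 1446; all 1162 shared), and code style with sex 1821 (800 higher). Sex alone gave 663 (293 and 370), averaging arrays with a shared code numeral (of different inferred sex, so not of 1 animal) 471 (196 and 275), replicates 1 and 2 alone 130 (60 and 70) and replicates 3 and 4 alone 418 (241 and 177); the last 3 use fewer samples, and the cause of the other shifts was not tested. Stricter rules gave 201 at adjusted p 0.01 (98 and 103), 292 with a log2 difference of at least 1 (124 and 168) and 113 with an ordinary variance (50 and 63), and 1 probe set per gene, with fewer tested, gave 441 lower. Leaving out 1 array gave 395 to 1744 calls (176 to 766 higher, 219 to 978 lower). The highest was without experimental replicate 2, and the cause was not tested. Median centring, quantile normalization, filters on dim probe sets, trended variance and array weights gave 1046 to 1534 calls. E2f2 at 1455790_at no longer passed with shared numerals averaged (-0.67, adjusted p = 0.0965), within replicates 1 and 2 (-0.63, 0.153) or 3 and 4 (-0.68, 0.161), or with sex as a block (-0.66, 0.0707). Its difference without 1 array lay between -0.73 and -0.57, and over all alternatives its adjusted p lay between 0.0172 and 0.161. E2f1 at 1431875_a_at passed with code style as a block (0.48, adjusted p = 0.0256) and with sex added (0.49, 0.0443; 0.0256 to 0.603 over all alternatives), and at 1417878_at its difference without 1 array lay between 0.37 and 0.79; the cause was not tested. Of the 24 gene lists, 0 passed with an estimated correlation. The estimate lay far above the preset 0.01 in the replication (0.34), mitosis (0.44), interferon (0.73) and ribosome (0.79) lists. Their camera values at the preset therefore rest on a correlation below that estimate. The p53 (-0.02), myeloid transcription factor (-0.04) and stem cell (0.005) lists, with estimates below the preset, lost their calls too. A higher correlation does not account for those losses. Camera with an estimated correlation also uses fewer degrees of freedom than at a preset one, which raises p whatever the correlation. How much of the losses this explains was not tested. With fry, which tests another hypothesis, 11 passed: 8 calls were lost, and the inflammatory list gained one (adjusted p = 0.0317; 0.0317 to 0.386 over the alternatives). Testing only probe sets with a mean of at least 6 ended 5 list calls (T and NK cell, megakaryocyte, myeloid transcription factor, stem cell and secondary granule) and testing only those above the median level ended 3 (the last 3 of these). Quantile normalization ended the stem cell call, and the mean or most variable probe set of a gene the secondary granule call. The monocyte list passed with median centring and with sex as a block. The cause of these changes was not tested. No list changed its call with replicate number or code style as a block, and the replicate block changed no call of a targeted probe set. The monocyte list reversed within replicates 3 and 4 (0.25), and the cause was not tested. Signal near background limits dim probe sets, and 1116 passed when only those with a mean of at least 6 were tested.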

Other observations

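All tests in this part except the counts over other splits of the arrays were chosen after the results they measure were seen. Histone probe sets were in no list fixed before the data were examined, were picked after their values were seen and were not tested for enrichment. Of 37, 15 fell, none rose and the others did not pass, with a median log2 difference of -0.52, while 696 of all 45037 probe sets fell. Examples were the linker histone gene H1f2 (-1.39 ± 0.14 SE at 1416101_a_at, adjusted p = 0.00266 by limma, n = 4 per group), H2ax (-1.06 ± 0.13) and H2ac19 (-1.38 ± 0.16 at 1418366_at), and 1460314_s_at, which carries several H3 gene names, fell by 2.11. Several of these probe sets share genes, so they are not independent. The actin ratio of 3' to 5' signal differed between the groups as well (0.44 against 0.30).

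Replication genes were higher while mitosis genes were lower in the same arrays. A larger share of cycling cells would raise both, but the mitosis list had a mean of -0.39, with every experimental array below every control. Each code style held 2 arrays of each group, so by design a shift common to a style could not raise the replication list. Within the styles its array means lay at least 0.44 and 0.52 apart between the groups. The unequal sexes are argued against for this list: each group held both sexes, and every experimental array (9.60 to 9.71) lay above every control (8.91 to 9.19). With both as blocks, 26 of the 26 replication genes that rose still rose. As 1080 of all 1162 calls were also kept, this count does not set the replication genes apart. All 26 lay above the median level, but each gene was represented by its brightest probe set. That outcome was close to fixed beforehand, so it does not decide whether dim signal plays a part. A change in the phases of the cell cycle that cells occupy, or in transcription of E2F targets in each cell, may underlie the pattern as a hypothesis. No test that separates these was run here. RNA integrity, by an actin ratio that separated the groups (0.44 against 0.30, while Gapdh did not), stays open too.

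Genes of B cells were lower in these Cd11b-positive cells. The T and NK cell list, which a purer sort that lowered every other cell type alike might also lower, did not fall. This does not decide the question, since the list holds NK cell genes and NK cells can carry Cd11b. The T and NK cell mean differed by 0.35 ± 0.25, against -1.16 ± 0.26 for the B cell list (SE of array means, not moderated). It did not separate the groups (two-sided exact permutation p = 0.257), and experimental replicate 2 (6.05) lay within the controls (5.99 to 6.69). A smaller loss of T and NK cells is therefore not excluded. The erythroid mean was 0.37, but 0.07 without experimental replicate 1. The megakaryocyte (-0.60) and dendritic cell (-0.57) lists were lower along with the B cell list, every experimental array below every control, so a loss of some other cell types stays open. B cell genes varied together between arrays of a group (mean correlation 0.406, against 0.188 at the 95th percentile of 1000 matched random lists), but so did replication (0.343) and mitosis genes (0.438), and megakaryocyte (0.143 against 0.148) and dendritic genes (0.0436 against 0.162) did not, so this does not single out a loss of cells. The brightest Ighm probe set, at 12.4, read 0.11 (95% confidence interval -0.73 to 0.94, list median -1.31), and 1427329_a_at (-0.12 ± 0.33 SE) and 1452535_at (0.35 ± 0.64) also lay more than 2 SE above that median, but 1425385_a_at (0.08 ± 1.25), 1425247_a_at (-0.87 ± 0.96), 1425324_x_at (-1.03 ± 1.13), 1427756_x_at (-0.82 ± 1.00) and 1427870_x_at (-0.64 ± 0.83) did not. The confidence interval given for Ighm joins the moderated SE with the residual degrees of freedom, so it is wider than that of the moderated fit. Ighm is also made by plasma cells, so fewer B lineage cells, which may account for the pattern, and lower expression in each cannot be told apart, and the genotype and RNA integrity stay untested causes.

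Genes near E2f2 were looked at as a group after Ncmap and Id3 had been seen among the changed genes. Among the 81 measured genes centred on E2f2 in the gene order of GRCm38.p6, 7 were past the threshold (Stmn1 -0.55, Selenon -0.67, Ncmap 2.83, Pnrc2 -0.82, Id3 -0.92, Tcea3 -0.999 and Zfp46 -0.60), and a share of 0.0333 of 16534 such windows held as many (0.00925, 0.0235 and 0.00562 with 10, 20 and 80 genes on either side). Without Ncmap and Id3 the share was 0.168 (0.0426, 0.162 and 0.00743), and without every gene named by the rule, anywhere, 0.0487 (0.0301, 0.123 and 0.00653). Around E2f1, null in both groups, and E2f3, floxed in both, it was 0.314 and 0.168 with all genes counted. DNA that came with the mutant E2f2 allele from another strain is a candidate explanation that cannot be told apart here from chance, since the share depends on the window and on the genes that prompted the test, or from loss of E2f2 itself, and no sequence was analysed here.

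Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many as 1162 calls. The highest other gave 35 and followed code style, and 32 gave none. A share of 1 in 35 is the smallest these splits can give, and they ignore the pairing, so chance is not excluded by it. Among the 8 splits that part all 4 same-numbered pairs, the highest other gave 0 calls, but 8 are too few for a share under 0.05. The remaining 27 leave some pairs together. For the gene lists, 1 of 35 splits gave as many as 18 past the threshold, but the highest other gave 16 (13 among splits that part all pairs). A large number of lists past the threshold at the preset correlation is therefore also reached by splits that mix the groups.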
